A study of Arabidopsis thaliana with 12 samples.

How the data were processed

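Total RNA from Arabidopsis thaliana seedlings harvested at 14 days was measured on 12 Affymetrix 1-colour arrays after biotin labelling as cRNA. The arrays fall into 4 groups of 3 biological replicates, made of 2 genotypes (Col-0 and xrn3-8) and 2 times (0 min, before treatment, and 60 min after 150 mg/l cordycepin was given). The labels list no mock-treated group at 60 min, so the effect of cordycepin and the effect of time and handling stand together in each comparison over time.

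The deposited values are log2 signals, 1 per probe set and array, rounded to 2 decimals. They range from 1.74 to 13.22. The 12 columns have nearly the same distribution, so the values had been normalized between arrays by the authors before deposition, and every change is relative to the average probe set of an array. The method of normalization, background correction and summary is not given in the sources used here. Per the submitters' processing notes, affy 1.48.0 and limma 3.26.9 were used. The median log2 signal was 4.86 to 4.87 in Col-0 before cordycepin, 4.68 to 4.69 in Col-0 after it, 4.80 to 4.81 in xrn3-8 before it and 4.63 to 4.69 in xrn3-8 after it. The number of arrays limits the precision. No detection calls were used here.

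Of 22810 probe sets, 64 are Affymetrix controls and were kept out of the tests, which left 22746. The probe table gives exactly 1 gene for 13513 of these and several genes for 503. Another 8730 are not listed in it; they were tested and counted, but they are unnamed here, not without a gene. Of the 13513 single-gene probe sets, 13436 were matched by Entrez gene identifier to the reference gene table (assembly TAIR10.1) and 77 were not. They stand for 13355 genes, 147 of them with more than 1 probe set, and the probe set with the highest mean over all arrays was used where 1 value per gene was needed. The reference gives 1535 of these genes a symbol other than the locus code; other genes are named by locus code alone. XRN3, XRN2 and XRN4 are not among the named probe sets, so the check of the genotype by the signal of XRN3 was not run.

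A model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 8 residual and 7.964 prior degrees of freedom). The following 5 contrasts were tested, all two-sided: xrn3-8 minus Col-0 before cordycepin, the same after cordycepin, after minus before cordycepin in each genotype, and the interaction of genotype and cordycepin (the change in xrn3-8 minus the change in Col-0). P values were adjusted by Benjamini and Hochberg over the 22746 probe sets of a contrast, and an adjusted p under 0.05 was called. The median SE of a log2 difference was 0.0960, and 0.136 for the interaction.

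The design, the tests, 25 gene lists and the rule for named genes were fixed before the data were examined. The rule takes, per contrast, the 6 largest rises and 6 largest falls among called single-gene probe sets whose 2 groups of arrays do not overlap (for the interaction, among all called ones), and 6 and 6 more among genes with a symbol. It adds up to 4 members with the largest change of each list described, and the 6 pairs of neighbouring genes in which 1 gene was most raised in xrn3-8. Of 371 members of the 25 lists, 49 have a named probe set, and 7 lists with at least 3 measured members were tested. These 7 hold cleavage and polyadenylation factors, RNA decay and exosome factors, early auxin genes, cold and drought genes, nuclear photosynthesis genes, cytosolic ribosomal protein genes and housekeeping genes. Another 39 lists of gene families and organelle genomes were written after the probe annotation was seen and before any fold change was looked at; among them is an extended list of 72 cytosolic ribosomal protein genes. The 46 lists were tested per contrast with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the 46 lists, and again with the correlation estimated per list and with fry.

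Neighbouring genes were taken from the order of genes in the reference table. That table gives no strand, so the planned test of the upstream neighbour on the same strand was not run as written. In its place, chosen after the files were seen, the mean log2 signal in Col-0 before cordycepin of the more strongly expressed flanking gene on either side was compared between genes called higher in xrn3-8 and all other genes by a permutation test (two-sided, 100000 permutations), with and without matching on the gene's own signal. The own signal was the mean over all 12 arrays, those of xrn3-8 included. Where a single flanking gene had a named probe set, that gene was used, and genes without any were left out. Adjacent pairs called in the same direction were counted against 10000 random draws of as many genes. Alternative settings covered the replicate number as a block, a signal-dependent prior variance, array weights, a filter that leaves out the 40% of probe sets with the lowest mean, stricter thresholds, probe sets that can cross-hybridize, each array left out in turn, fits of only the 2 groups compared, and 4 other scalings. The scalings were quantile normalization applied again, and centring of each array on 7 housekeeping and ribosomal protein genes, on 12 Bacillus subtilis control probe sets with a signal above 4, or on 18 hybridization control probe sets; the last 2 were chosen after the files were seen. Random steps used seed 7. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

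The procedure was tested on simulated data with 22746 probe sets, of which 200 were changed. At a log2 change of 0.5, it recovered 92.0% of the changed probe sets for genotype before cordycepin, 86.0% for genotype after cordycepin, 70.0% for cordycepin in Col-0, 84.0% for cordycepin in xrn3-8 and 30.0% for the interaction. At a log2 change of 1, it recovered 100.0%, 98.0%, 100.0%, 100.0% and 98.0% in the same order, and at 0.25 it recovered 4.0%, 10.0%, 12.0%, 0.0% and 4.0%. The adjustment is stricter where few probe sets change, and the real contrasts called 1830 to 10534 probe sets. These shares therefore do not give the sensitivity in the real contrasts. False calls made up 3.9%, 4.5%, 9.0%, 4.7% and 3.3% of the calls. A shifted list was called in each of the 5 simulated contrasts, with 1 unshifted list called in the interaction and 0 in the other contrasts. The flanking gene test, run on 8367 genes, called 4.0% of 100 simulations without a shift (3.0% with matching) and 98.0% of those with a shift of 1 (98.0% with matching). The count of adjacent pairs, run on 13355 genes, called 3.0% of the simulations without a shift.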

Results

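Transcript levels were measured in whole seedlings of Col-0 and of the line carrying the xrn3-8 allele, before and 60 min after the addition of cordycepin. Cordycepin is an adenosine analogue that stops the growth of RNA chains. XRN3 is a nuclear exoribonuclease that degrades the RNA still attached to RNA polymerase after a transcript has been cleaved. The series asks how a mutation of XRN3 alters the expression of protein-coding genes. Whether the xrn3-8 allele removes XRN3 was not checked here. There were 3 arrays in each of the 4 groups and 22746 probe sets were tested on each. Within a group, the correlation of log2 signals between arrays was 0.995 to 0.998. The first principal component held 52.9% of the variance and the second 31.8%.

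**Figure D1:**
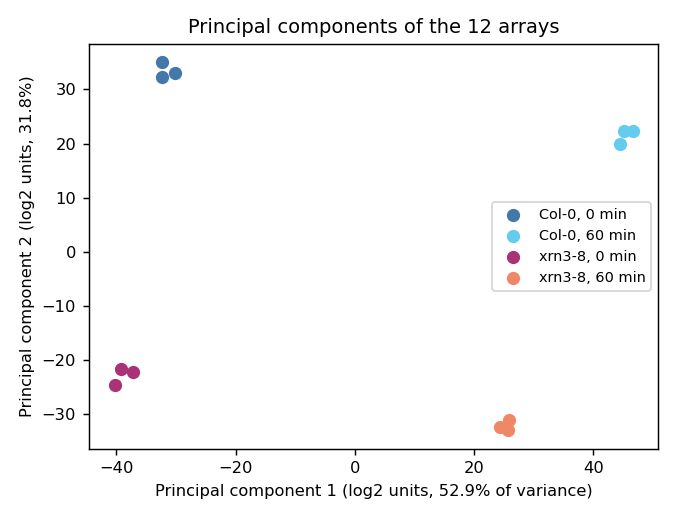
Positions of the 12 arrays on the first (x axis, 52.9% of variance) and second (y axis, 31.8%) principal components of the log2 signals of all tested probe sets. Each point is 1 array and colours mark the 4 groups of 3. The arrays of a group lie together and apart from those of the other groups.

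The first comparison asked which transcripts differ between the genotypes before transcription was stopped. Among probe sets with 1 named gene, the largest rise in xrn3-8 was that of AT1G76170, whose mean log2 signal was 4.82 in Col-0 and 9.07 in xrn3-8 (log2 fold change 4.25 ± 0.11 SE, n = 3 arrays per group, adjusted p = 2.43e-13). AT2G41445 (3.89 ± 0.17), AT5G01700 (3.81 ± 0.08), AT2G18100 (3.17 ± 0.12), AT1G72420 (3.13 ± 0.11) and AT3G02480 (2.997 ± 0.20) came next. Among genes with a symbol, NRPD7, which encodes a subunit of a plant-specific RNA polymerase, rose by 2.80 ± 0.11 and the orphan gene QQS by 2.70 ± 0.08. The thionin gene THI2.2 rose by 2.61 ± 0.11 and the senescence-associated gene SAG29 by 2.51 ± 0.15. The tetraspanin gene TET9 (2.39 ± 0.13) and the defensin-like gene PDF2.1 (2.21 ± 0.18) were also higher. Among the same probe sets, the largest decrease was that of AT1G26250, with a mean log2 signal of 7.51 in Col-0 and 2.68 in xrn3-8 (-4.83 ± 0.12, adjusted p = 1.21e-13). It was followed by AT1G64590 (-3.80 ± 0.19), AT1G26390 (-3.63 ± 0.16), AT2G15220 (-3.43 ± 0.15, on a probe set that can cross-hybridize), AT3G13610 (-3.17 ± 0.13) and AT1G26380 (-3.12 ± 0.15). The lower mean of AT1G26250, AT1G26390 (2.92), AT2G41445 (2.89) and CCOAMT (2.83) lay below the lower quartile of the arrays (2.98 to 3.02), near background, so the size of these changes is a lower bound.

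Lower in xrn3-8 among genes with a symbol were the methyltransferase gene CCOAMT (-3.01 ± 0.10), CHI (AT2G43570, -2.99 ± 0.12) and the osmotin-like gene OSM34 (-2.80 ± 0.14). The isocitrate lyase gene ICL of the glyoxylate cycle (-2.56 ± 0.12), the glutathione transferase gene GSTU22 (-2.13 ± 0.14) and the transporter gene OCT1 (-1.82 ± 0.17) were also lower. In all, 7264 probe sets were called, 3256 higher and 4008 lower in xrn3-8, or 44.8% higher. Of these, 275 were at least 2-fold higher and 317 at least 2-fold lower, and the extremes, 5.28 and -5.64, were on probe sets unnamed here. The balance of directions depended on the scaling, since 61.4% of the 6474 probe sets called after centring on Bacillus subtilis controls were higher, and 38.2% of the 7258 called after centring on housekeeping and ribosomal protein genes.

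Genes of cytosolic ribosomal proteins were higher in xrn3-8 as a group. Of the 72 members of the extended list, 48 rose and 0 fell, with a median of 0.28. Of these, AT2G40010 (0.86 ± 0.09), AT5G47700 (0.67 ± 0.09), AT4G00810 (0.66 ± 0.13) and AT4G39200 (0.60 ± 0.08) rose most. The camera test gave an adjusted p of 1.01e-14 for this list, but adjusted p = 0.0622 with an estimated correlation. The median was 0.25 to 0.37 under the 4 other scalings, with 58 members called higher under Bacillus subtilis centring and 14 under hybridization control centring. No other list of the 46 was called, whereas fry called 18. Among 69 genes of the plastid genome, 15 were lower, with psbD (-1.14 ± 0.16) and psbC (-1.14 ± 0.11), which encode photosystem II proteins, at the bottom. Another 2 were higher, among them petG (0.44 ± 0.11), and the camera adjusted p of the plastid list was 0.121. Of the lists fixed in advance, the RNA decay and exosome list had 1 member lower of 9 (UPF3, -0.33 ± 0.08), and 1 when adjusted over the list alone. In the cold and drought list, COR15B was higher (0.87 ± 0.12), COR47 was lower (-0.37 ± 0.07) and COR15A did not pass. The counts adjusted over the list alone were also 1 and 1, and the median (-0.07) and mean (0.14) differed in sign. The planned ribosomal protein list of 3 had 1 member higher (AT3G53890, 0.27 ± 0.07), and 1 when adjusted over the list alone. The cleavage and polyadenylation, early auxin, photosynthesis and housekeeping lists had 0 called members, and 0 when adjusted over the list alone.

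The title of the series names transcription termination, so the genes beside those raised in xrn3-8 were examined. AT1G76170, AT2G41445 and AT1G72420 had no measured flanking gene. AT5G01700, with a log2 signal of 3.76 in Col-0, lies beside AT5G01710, with 10.42, and AT2G18100 (3.79) lies beside AT2G18090 (8.43). AT3G02480 (3.48) lies beside SAMDC (11.82), which encodes an enzyme of polyamine synthesis, and AT4G27270 (5.02) lies beside AT4G27280 (11.18). While AT5G01700 rose by 3.81, AT5G01710 fell by 0.44 ± 0.08, and AT4G27280 rose by 0.30 ± 0.11 against 2.87 ± 0.09 for AT4G27270. AT2G18090 (-0.09 ± 0.10, adjusted p = 0.584) and SAMDC (-0.18 ± 0.07, adjusted p = 0.0732) did not pass the test. The other pairs in the set were AT1G56670 (2.72 ± 0.14) beside AT1G56660 (4.51 in Col-0, change 0.67 ± 0.20) and AT1G73510 (2.67 ± 0.11) beside AT1G73530 (6.43 in Col-0, change 0.92 ± 0.09). AT1G73510 itself stood at 2.29 in Col-0, below the lower quartile of the arrays, so its rise is a lower bound.

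Of 139 genes at least 2-fold higher in xrn3-8, 80 had a measured flanking gene. For these 80, the stronger measured flanking gene had a mean log2 signal of 6.34 (SD 2.79), against 5.10 (SD 2.23) for the 8287 other genes. The difference was 1.23 (permutation p = 1.00e-05, the smallest that the permutations can give). The flanking signal exceeded that of genes matched on their own signal by 0.998 (permutation p = 8.00e-05). Among genes with a measured flanking gene, a flanking signal over 8 was found for 30% of these 80. The share was 9.3% of the 108 genes at least 2-fold lower and 10.7% of the 5899 genes called in neither direction. Of 1733 genes called higher, 1150 had a measured flanking gene. Their flanking signal was 5.51 against 5.05 for 7217 other genes (difference 0.45, permutation p = 1.00e-05), but 0.14 above matched genes (permutation p = 0.0558). Of 2111 genes called lower, 1318 had a measured flanking gene. For these the difference was 0.35 (permutation p = 1.00e-05), and 0.04 from matched genes (permutation p = 0.588). Adjacent genes were both called higher in 130 pairs, against 88.93 in random draws (highest 128, permutation p = 1.00e-04, the smallest that the draws can give). Genes at least 2-fold higher formed 1 such pair against 0.56 (permutation p = 0.426), and genes called lower formed 143 against 129.65 (permutation p = 0.116), or 197 against 166.86 between protein-coding neighbours (permutation p = 0.00780). The strand of the genes is not given in the reference used here, so upstream and downstream neighbours were not separated.

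**Figure D2:**
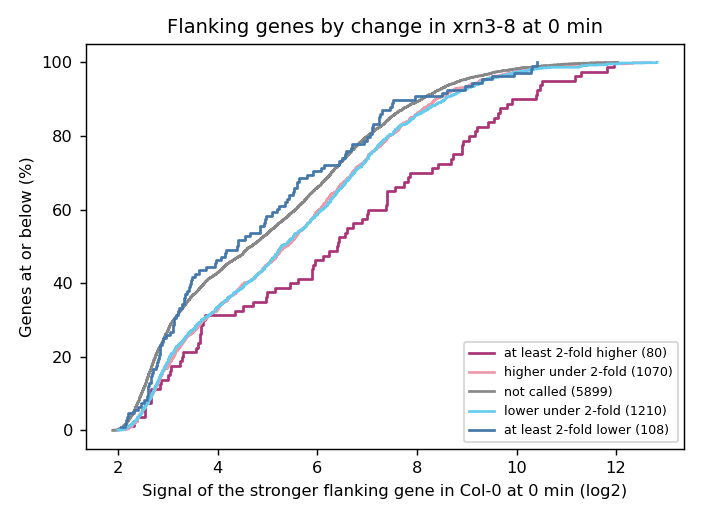
Cumulative share of genes with a measured flanking gene (y axis) by the mean log2 signal, in Col-0 before cordycepin, of the more strongly expressed flanking gene (x axis). Each line is a set of genes, which were at least 2-fold higher (80), higher by less, at least 2-fold lower (108), lower by less or not called (5899) in xrn3-8 before cordycepin. The line of the 80 genes at least 2-fold higher lies to the right, with 30% of them beside a gene with a signal over 8, against 10.7% of genes not called.

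The second comparison asked whether the genotypes still differ 60 min after cordycepin. THI2.2 (2.88 ± 0.11), QQS (2.79 ± 0.08), AT2G41445 (2.44 ± 0.17), AT1G65490 (2.40 ± 0.09), AT3G13760 (2.37 ± 0.10) and SAG29 (2.37 ± 0.15) were the most raised in xrn3-8 among probe sets with 1 named gene (n = 3 arrays per group). Next among genes with a symbol were the subtilase gene SBT3.3 (2.32 ± 0.11), TET9 (2.06 ± 0.13) and the cytochrome P450 gene CYP71B26 (2.003 ± 0.12). The most reduced among them were AT1G26250 (-4.53 ± 0.12, adjusted p = 4.40e-13), AT1G26390 (-3.61 ± 0.16), AT2G15220 (-3.46 ± 0.15), OSM34 (-3.44 ± 0.14), AT5G22555 (-3.33 ± 0.11) and AT3G13610 (-3.18 ± 0.13). CCOAMT (-2.97 ± 0.10), CHI (-2.90 ± 0.12), ICL (-2.79 ± 0.12), the cell-wall invertase family gene cwINV6 (-2.22 ± 0.10) and the peroxidase gene Prx37 (-2.09 ± 0.14) were lower as well. The lower means of AT1G26250 (2.94), AT5G22555 (2.8) and AT2G41445 (3.01) lay below the lower quartile of the arrays (3.05 to 3.1), so these changes are lower bounds too.

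After cordycepin, 7322 probe sets differed between the genotypes, 3771 higher and 3551 lower in xrn3-8, or 51.5% higher, with extremes of 3.07 and -5.22 on probe sets unnamed here. Centring on Bacillus subtilis controls, which moved the median of all probe sets to -0.12, gave 7591 calls with 25.7% higher, centring on hybridization controls 4742 with 36.7% higher, and centring on housekeeping and ribosomal protein genes 7443 with 60% higher. Between the comparisons before and after cordycepin, which share no array, 4268 probe sets were called in the same direction. These were 2052 higher in both (539.8 expected by chance) and 2216 lower in both (625.7 expected), while 182 were called in opposite directions. With hybridization control centring 2587 were shared, 1008 higher in both (143.0 expected) and 1579 lower in both (336.5 expected). Across probe sets, which are not independent replicates, Pearson's r of the log2 fold changes was 0.743. Of 139 genes at least 2-fold higher in xrn3-8 before cordycepin, 110 were still called higher after it and 65 still at least 2-fold, with a median of 1.36 before and 0.93 after. Of 164 genes at least 2-fold lower, 160 were still called lower and 114 still at least 2-fold, with a median of -1.34 before and -1.44 after.

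None of the 46 lists was called by camera between the genotypes after cordycepin, with 0 also with an estimated correlation, whereas fry called 16. Of the cleavage and polyadenylation list, AT5G60940 (0.62 ± 0.14) and FY (0.35 ± 0.10) were higher and 4 members did not pass. The photosynthesis list had LHCB4.2 (0.76 ± 0.10) and RCA (0.22 ± 0.07), the gene of Rubisco activase, higher. In the cold and drought list COR15B was higher (0.44 ± 0.12) while COR15A (-0.69 ± 0.15) and COR47 (-0.28 ± 0.07) were lower. AT3G46960 (0.37 ± 0.10) was higher and UPF3 (-0.25 ± 0.08) lower among RNA decay factors, and GAPC2 (0.26 ± 0.07) was higher among housekeeping genes. Counts adjusted over the list alone were 2 of 6 for cleavage and polyadenylation, 2 of 4 for photosynthesis, 3 of 3 for cold and drought, 2 of 9 for RNA decay and 1 of 4 for housekeeping, the same numbers as over all genes. The early auxin and planned ribosomal protein lists had 0 called members on both counts. The median of the extended ribosomal protein list was 0.07, turning to -0.07 with Bacillus subtilis centring and to -0.01 with hybridization control centring.

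The comparison of Col-0 before and after cordycepin asked which transcripts were lost or gained, relative to the average of the array, within 60 min. The largest decreases were those of AT5G61590 (mean log2 signal 9.26 before and 4.72 after, -4.54 ± 0.14 SE, n = 3 arrays per group, adjusted p = 3.07e-13), AT3G19680 (-4.16 ± 0.09), AT3G06070 (-4.14 ± 0.10), AT5G01740 (-4.10 ± 0.09), AT5G07580 (-3.88 ± 0.11) and AT5G25280 (-3.88 ± 0.10). The expansin-like gene EXLA2 (-3.01 ± 0.11), the organ size gene ARL (-2.57 ± 0.09) and the zinc finger factor gene STZ (-2.56 ± 0.08) fell too. So did the homeodomain factor gene HAT2 (-2.53 ± 0.11), GAT1_2.1 (-2.47 ± 0.11) and UGT85A2 (-2.20 ± 0.09). Rises were smaller, led by AT5G01700 (2.72 ± 0.08), AT2G18100 (2.02 ± 0.12), AT5G39020 (2.003 ± 0.10), AT5G47980 (1.99 ± 0.10), AT3G26460 (1.703 ± 0.15) and AT5G22540 (1.67 ± 0.13). The defensin gene PDF1.2 (1.16 ± 0.11), TRM31 (1.12 ± 0.12), the glutathione transferase gene ATGSTF13 (1.09 ± 0.12), the cold-regulated gene COR15A (1.04 ± 0.15), DLAH (1.04 ± 0.09) and the phosphatase gene POL (1.02 ± 0.14) were also higher.

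In Col-0, 10534 probe sets changed after cordycepin, 5973 higher and 4561 lower, but 1187 were at least 2-fold lower and 122 at least 2-fold higher. The share of calls that were higher was 56.7% as deposited, 8.23% of 14297 with centring on housekeeping and ribosomal protein genes, 3.56% of 16304 with Bacillus subtilis centring and 19.4% of 6732 with hybridization control centring. The median of all probe sets was 0.07 as deposited and -0.28, -0.39 and -0.12 under these 3 scalings, so that small rises are relative to a falling or constant average, depending on the scaling. The genes with the largest changes, named above, kept their direction under all 4 other scalings, but they were chosen for their size on these arrays. Of 20 called members of the lists fixed in advance, 7 changed sign under at least 1 scaling.

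Early auxin genes, a list fixed in advance, were lower in Col-0 after cordycepin. Of 4 measured members, GH3.3 (-1.51 ± 0.13) and WES1 (-0.95 ± 0.10), which encode enzymes that conjugate auxin to amino acids, and IAA29 (-1.03 ± 0.13), a repressor of auxin responses, fell, while AT2G18010 (0.01 ± 0.09), at a background-level mean signal of 2.41, did not pass. The count was also 3 when adjusted over the list alone. The camera adjusted p of the list was 0.0207, and adjusted p = 0.245 with an estimated correlation and 0.0695 with centring on housekeeping and ribosomal protein genes. Calmodulin-like genes were lower in 6 of 7 cases, led by CML38 (-1.96 ± 0.10) and CML37 (-1.697 ± 0.10), and the median was -0.71 (adjusted p = 1.19e-04, and adjusted p = 0.167 with an estimated correlation). Plant U-box ubiquitin ligase genes were lower in 6 of 9 cases and higher in 2, with PUB26 (-1.47 ± 0.10), PUB23 (-1.39 ± 0.08) and PUB22 (-1.05 ± 0.11) the most reduced (adjusted p = 0.00175, and adjusted p = 0.167 with an estimated correlation). Of 47 genes of UDP-glycosyltransferases, 22 were lower and 5 higher, with UGT85A2 (-2.20 ± 0.09), UGT74B1 (-1.92 ± 0.08), UGT88A1 (-1.21 ± 0.09) and UGT73B1 (-1.18 ± 0.12) at the bottom (adjusted p = 0.00157, and adjusted p = 0.245 with an estimated correlation). Of 14 bZIP factor genes, 6 were lower and 1 higher, among them BZIP61 (-1.96 ± 0.12) and the unfolded protein response genes BZIP60 (-1.93 ± 0.08) and BZIP28 (-1.16 ± 0.09) (adjusted p = 0.0207, and adjusted p = 0.188 with an estimated correlation).

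Cytosolic ribosomal protein genes of the extended list were higher after cordycepin in Col-0 in 58 of 72 cases, with 0 lower, and had a median of 0.35 (0.17 in lists matched on signal, central range 0.06 to 0.26), which turned to -0.11 with Bacillus subtilis centring (2 higher and 14 lower). Centring on 7 housekeeping and ribosomal protein genes brought it to -0.01 (6 higher and 9 lower). Some of these 7 encode ribosomal proteins, so that centring is not independent of the list. The adjusted p was 7.87e-10, and adjusted p = 0.167 with an estimated correlation. AT5G47930 (0.73 ± 0.08) and AT5G39850 (0.69 ± 0.07) rose most. Tubulin genes were higher in 6 of 7 cases, led by TUB1 (0.63 ± 0.11) and TUB9 (0.60 ± 0.09), with a median of 0.53 (adjusted p = 0.0207, and adjusted p = 0.245 with an estimated correlation and 0.131 with hybridization control centring). The tubulin median was 0.07 with Bacillus subtilis centring, where 0 were higher and 2 lower, and 0.18 with centring on housekeeping and ribosomal protein genes, where 2 were higher and 1 lower. Among lists fixed in advance that camera did not call, COR15A, COR15B (0.76 ± 0.12) and COR47 (0.30 ± 0.07, but -0.16 with Bacillus subtilis centring), all 3 measured cold and drought genes, were higher, and 3 when adjusted over the list alone (adjusted p of the list 0.119). The planned ribosomal protein list had 3 of 3 higher on both counts and the housekeeping list 3 of 4 on both counts, and their medians of 0.38 each turned to -0.08 with Bacillus subtilis centring. Of cleavage and polyadenylation genes, AT4G25550 (0.49 ± 0.09) and AT5G65260 (0.29 ± 0.09) were higher on both counts, while with Bacillus subtilis centring AT5G65260 turned to -0.17 and the median of the list, 0.17, to -0.29. Of RNA decay genes, RRP41 (-0.45 ± 0.10), UPF3 (-0.36 ± 0.08), AT1G54440 (-0.35 ± 0.09) and LSM1B (-0.26 ± 0.08) were lower and AT5G35910 (0.32 ± 0.13, but -0.14 with Bacillus subtilis centring) higher, 4 and 1 also over the list alone. LHCB4.2 (-1.27 ± 0.10) was the 1 photosynthesis gene called on either count, and the median (0.01) and mean (-0.30) of that list differed in sign.

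Cordycepin in xrn3-8 was compared in the same way. AT5G61590 (8.91 before and 4.44 after, -4.47 ± 0.14 SE, n = 3 arrays per group, adjusted p = 7.31e-13), AT4G10270 (-4.38 ± 0.13), AT3G55840 (-3.78 ± 0.15), AT4G28240 (-3.71 ± 0.10), AT5G25280 (-3.67 ± 0.10) and AT3G19680 (-3.55 ± 0.08) had the largest decreases. STZ (-2.55 ± 0.08), ARL (-2.23 ± 0.09), NRPD7 (-2.16 ± 0.11), the RING finger gene BRH1 (-2.09 ± 0.09), CML37 (-2.09 ± 0.10) and CML38 (-1.94 ± 0.10) were also lower. The largest rises were those of AT5G48430 (1.65 ± 0.17), AT2G44010 (1.49 ± 0.12), AT2G42350 (1.43 ± 0.09), AT5G11850 (1.38 ± 0.13), POL (1.36 ± 0.14) and AT4G16100 (1.35 ± 0.10). The co-chaperone gene Hop3 (1.11 ± 0.17), the endocytosis gene TPLATE (1.03 ± 0.11), the small heat shock protein gene ATHSP22.0 (1.01 ± 0.13), the plastid RNA polymerase gene rpoB (0.93 ± 0.20) and ATGP4 (0.91 ± 0.09) were higher. The rise of rpoB lost its call under Bacillus subtilis centring (0.24, adjusted p = 0.233).

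In xrn3-8, 9183 probe sets changed after cordycepin, 5570 higher and 3613 lower, with 846 at least 2-fold lower and 45 at least 2-fold higher. The share of calls that were higher was 60.7% as deposited, 9.88% of 10123 with centring on housekeeping and ribosomal protein genes, 0.29% of 21166 with Bacillus subtilis centring and 7.01% of 5848 with hybridization control centring. The median of all probe sets was 0.09, -0.19, -0.60 and -0.17 in that order. Between Col-0 and xrn3-8, whose comparisons share no array, 3707 probe sets were higher in both (1462.7 expected by chance), 2932 lower in both (724.5 expected) and 120 changed in opposite directions. At least 2-fold, 685 were lower in both and 23 higher in both, and Pearson's r across probe sets was 0.840.

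Early auxin genes were lower in xrn3-8 as well, with GH3.3 (-1.40 ± 0.13), WES1 (-1.27 ± 0.10) and IAA29 (-1.0 ± 0.13) called and AT2G18010 (0.07 ± 0.09) not, and 3 called when adjusted over the list alone. The camera adjusted p was 0.00747, and adjusted p = 0.254 with an estimated correlation. Plant U-box ligase genes were lower in 6 of 9 cases, with PUB26 (-1.61 ± 0.11), PUB23 (-1.27 ± 0.08) and PUB22 (-1.20 ± 0.11) the most reduced (adjusted p = 5.58e-04, and adjusted p = 0.237 with an estimated correlation). Calmodulin-like genes were lower in 4 of 7 cases, with CML23 (-0.98 ± 0.10) next after CML37 (-2.09 ± 0.10) and CML38 (-1.94 ± 0.10) (adjusted p = 0.00566, and adjusted p = 0.282 with an estimated correlation). Of 47 UDP-glycosyltransferase genes, 17 were lower and 5 higher, with UGT74B1 (-1.80 ± 0.08) and UGT73B1 (-1.54 ± 0.12) at the bottom (adjusted p = 0.0169, and adjusted p = 0.410 with an estimated correlation and 0.145 with Bacillus subtilis centring). Of 14 bZIP factor genes, 6 were lower, led by BZIP60 (-1.66 ± 0.08) and BZIP61 (-1.61 ± 0.12), and 2 higher (adjusted p = 0.0213, and adjusted p = 0.254 with an estimated correlation). Expansin genes, of proteins that loosen cell walls, were lower in 6 of 18 cases and higher in 2, with EXLA2 (-1.81 ± 0.11), EXLA3 (-1.41 ± 0.14), EXPA8 (-1.02 ± 0.13) and EXLA1 (-0.93 ± 0.10) at the bottom (adjusted p = 0.0345, and adjusted p = 0.282 with an estimated correlation and 0.305 with Bacillus subtilis centring).

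Among the families with rises in xrn3-8, 28 of 69 plastid genome genes were higher and 4 lower, with a median of 0.22 that turned to -0.06 with centring on housekeeping and ribosomal protein genes, -0.47 with Bacillus subtilis centring and -0.05 with hybridization control centring. The genes rpoB (0.93 ± 0.20), atpI (0.89 ± 0.20), psbD (0.74 ± 0.16) and rpoC2 (0.68 ± 0.17) rose most, and rps18 (-0.54 ± 0.12) and matK (-0.46 ± 0.10) were lower. On the same arrays the 25S ribosomal RNA control, also not a nuclear messenger RNA, rose by 2.53 ± 0.27. The adjusted p of the plastid list was 0.0169, and adjusted p = 0.548 with an estimated correlation. The extended ribosomal protein list had 20 members higher and 1 lower, with AT3G13580 (0.55 ± 0.10) and AT2G40010 (0.54 ± 0.09) at the top. Lists of genes matched on signal had a median of 0.19 (central range 0.11 to 0.24), and the ribosomal protein list had a median of 0.13 that turned to -0.56 with Bacillus subtilis centring and -0.13 with hybridization control centring (adjusted p = 0.0345, and adjusted p = 0.452 with an estimated correlation, 0.927 and 0.187 under these 2 scalings). All 7 tubulin genes were higher, led by TUB9 (0.49 ± 0.09) and TUA1 (0.48 ± 0.10), with a median of 0.41 that turned to -0.28 with Bacillus subtilis centring (adjusted p = 0.0169, and adjusted p = 0.306 with an estimated correlation and 0.116 with hybridization control centring). Among lists fixed in advance, COR15A (0.43 ± 0.15), COR47 (0.39 ± 0.07) and COR15B (0.33 ± 0.12) were higher, 3 of 3 also over the list alone, and their median of 0.39 turned to -0.30 with Bacillus subtilis centring (adjusted p of the list 0.25). The counts over all genes and adjusted over the list alone were both 4 of 6 higher for cleavage and polyadenylation, 2 higher and 2 lower of 9 for RNA decay, 1 of 4 lower for photosynthesis, 1 of 3 higher for the planned ribosomal proteins and 3 of 4 higher for housekeeping. With Bacillus subtilis centring the medians of the lists other than photosynthesis turned from above to below 0, and 13 of 19 called members of the lists fixed in advance changed sign under at least 1 scaling.

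**Figure D3:**
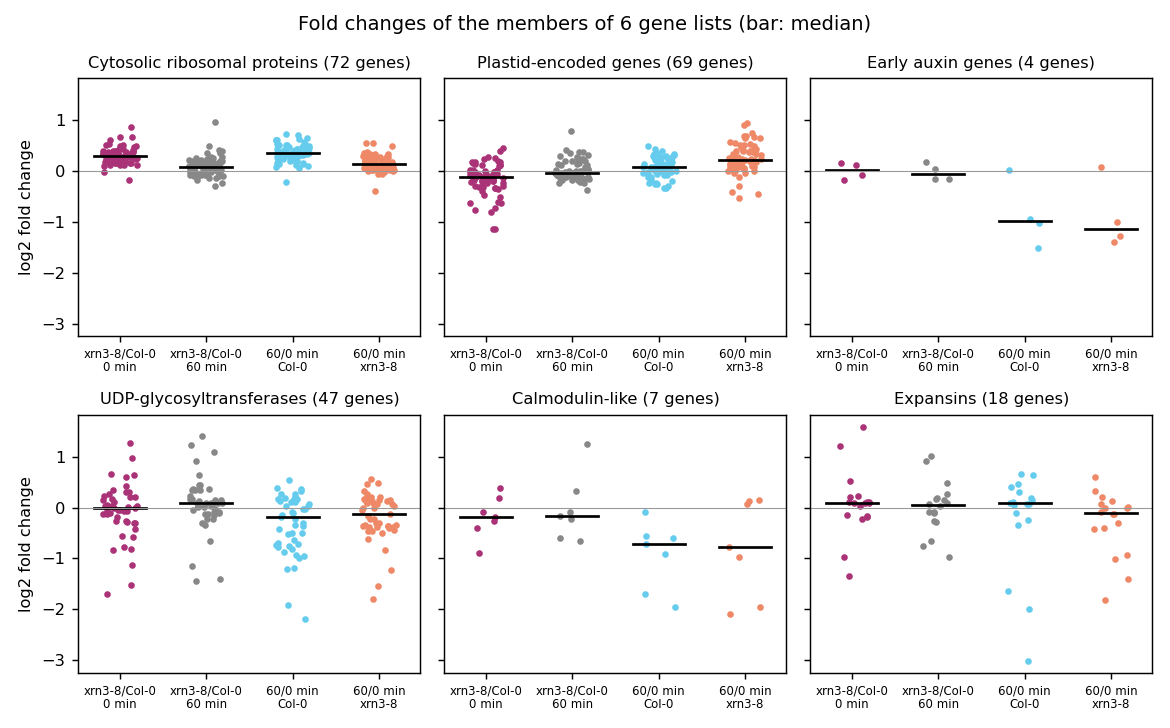
Log2 fold change (y axis) of the members of 6 gene lists (1 panel each) in the 2 genotype comparisons and the 2 cordycepin comparisons (x axis); each point is 1 gene and the bar is the median. Calmodulin-like genes had medians of -0.71 in Col-0 and -0.78 in xrn3-8 after cordycepin, whereas the ribosomal protein medians of 0.35 and 0.13 turned to -0.11 and -0.56, and the plastid median of 0.22 in xrn3-8 to -0.47, with Bacillus subtilis centring.

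The last comparison asked whether the change after cordycepin differed between the genotypes. AT5G01700 rose by 2.72 in Col-0, from 3.76 to 6.48, while it was already at 7.57 in xrn3-8 and stood at 6.58 after cordycepin. The interaction of AT5G01700 was -3.71 ± 0.11 SE (n = 3 arrays per group, adjusted p = 9.13e-12). AT2G18100 went from 3.79 to 5.81 in Col-0 and from 6.96 to 6.46 in xrn3-8 (-2.51 ± 0.16), and AT4G27270 from 5.02 to 5.88 in Col-0 and from 7.89 to 6.35 in xrn3-8 (-2.40 ± 0.13). AT1G74400 (-2.58 ± 0.15), AT1G76170 (-2.34 ± 0.16), AT1G19190 (-2.31 ± 0.22) and NRPD7 (-2.06 ± 0.15) also had negative interactions. AT1G76170 decreased from 9.07 to 6.62 in xrn3-8 while its means in Col-0 were 4.82 and 4.71. Among genes with a symbol, NRPD7 was followed by the carrier gene MBAC1 (-1.28 ± 0.12), the iron deficiency factor gene BHLH101 (-1.08 ± 0.19), the expansin gene EXPA4 (-1.04 ± 0.16), the methionine aminopeptidase gene MAP1B (-1.0 ± 0.15) and PDF1.2 (-0.90 ± 0.16).

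Positive interactions, in which the change in xrn3-8 exceeded that in Col-0, were largest among probe sets with 1 named gene for AT3G13760 (1.68 ± 0.15), whose mean fell from 5.09 to 3.497 in Col-0 and was 5.78 and 5.87 in xrn3-8. AT4G32350 (1.52 ± 0.15), AT1G51090 (1.39 ± 0.11), AT1G22810 (1.39 ± 0.14), AT1G54050 (1.36 ± 0.19) and AT3G62590 (1.35 ± 0.19) came next. EXLA2 (1.197 ± 0.15), the endosomal sorting gene ELC (1.14 ± 0.13), KICP-02 (1.14 ± 0.11), the cell wall gene XTH33 (1.13 ± 0.15), psbD (0.98 ± 0.23, adjusted p = 0.0138) and UGT85A2 (0.97 ± 0.12) were positive as well. In all, 1830 probe sets had an interaction, 1155 positive and 675 negative, or 63.1% positive, with extremes of 2.26 and -4.16 on probe sets unnamed here. At a size of at least 2-fold the balance turned, with 72 positive and 110 negative. The share was 79.7% of 2319 with centring on housekeeping and ribosomal protein genes, 10.8% of 2845 with Bacillus subtilis centring, which moved the median of all probe sets to -0.21, and 38.4% of 607 with hybridization control centring.

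Of the 139 genes at least 2-fold higher in xrn3-8 before cordycepin, 62 had a negative interaction and 11 a positive one. Of the 164 genes at least 2-fold lower, 28 had a positive interaction and 15 a negative one. In 100 simulations in which the genotype difference was the same at both times, the highest of these 4 counts was 0, 0, 1 and 1. The simulations held no interaction in any probe set, so few calls were bound to pass the adjustment. The genes were also chosen by the difference before cordycepin, which enters the interaction with a minus sign. The simulations cannot measure how far that choice tilts the observed counts. The extended ribosomal protein list was the 1 list called, with a median interaction of -0.205 and 6 of 72 members called, all negative (14 when adjusted over the list alone). Among them were AT5G47700 (-0.59 ± 0.12) and AT5G47930 (-0.46 ± 0.12). The median was -0.43, -0.13 and -0.27 with Bacillus subtilis, housekeeping and ribosomal protein, and hybridization control centring, with 40, 1 and 0 members called. The adjusted p of the list was 5.79e-11, and adjusted p = 0.148 with an estimated correlation. Of the lists fixed in advance, FY (0.49 ± 0.15) was the 1 called cleavage and polyadenylation gene and LHCB4.2 the 1 called photosynthesis gene on both counts, and 1 planned ribosomal protein gene was called on both. For RNA decay, 1 gene was called over all genes and 2 when adjusted over the list alone, and for cold and drought the counts were 0 and 2. Early auxin and housekeeping genes had 0 on both counts.

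**Figure D4:**
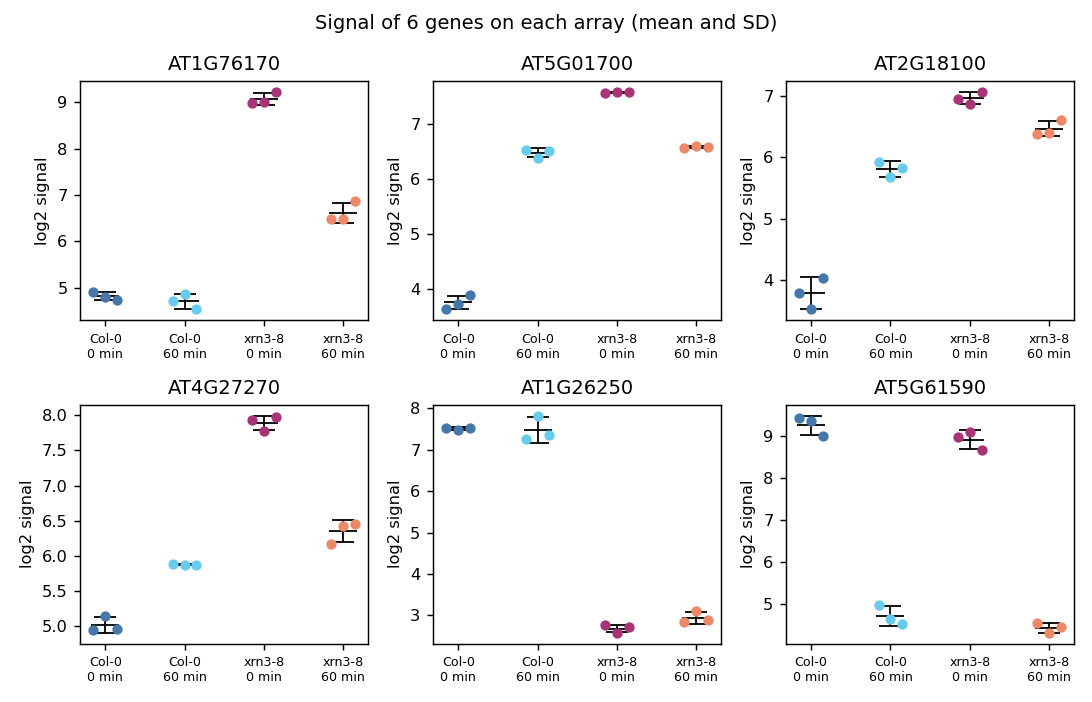
Log2 signal (y axis) of 6 genes on each array (points) by group (x axis), with the mean and SD of 3 arrays as bars. AT5G01700 stood at 3.76 in Col-0 and 7.57 in xrn3-8 before cordycepin and at 6.48 and 6.58 after it, and AT5G61590 decreased from 9.26 to 4.72 in Col-0 and from 8.91 to 4.44 in xrn3-8.

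Control probe sets were kept out of these tests. The Bacillus subtilis controls averaged 4.91 ± 0.04 (SD, n = 3) in Col-0 before cordycepin and 5.37 ± 0.10 after it, and 4.83 ± 0.07 and 5.52 ± 0.01 in xrn3-8. The hybridization controls averaged 8.07 ± 0.13 and 8.26 ± 0.14 in Col-0 and 8.08 ± 0.08 and 8.34 ± 0.17 in xrn3-8. The array holds 2 sets of actin and GAPDH controls, with different probes at the end and the start of the transcript. The excess of the end over the start was 3.47 and 3.29 in Col-0 and 3.31 and 3.29 in xrn3-8, before and after cordycepin, for the first actin set and 0.94, 0.95, 0.93 and 1.02 for the second. For the first GAPDH set it was 0.33 ± 0.12 (SD, n = 3), 0.05 ± 0.04, 0.12 ± 0.08 and 0.09 ± 0.18 in the same order, and for the second -0.13 ± 0.07, -0.23 ± 0.03, -0.13 ± 0.05 and -0.08 ± 0.10.

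**Figure D5:**
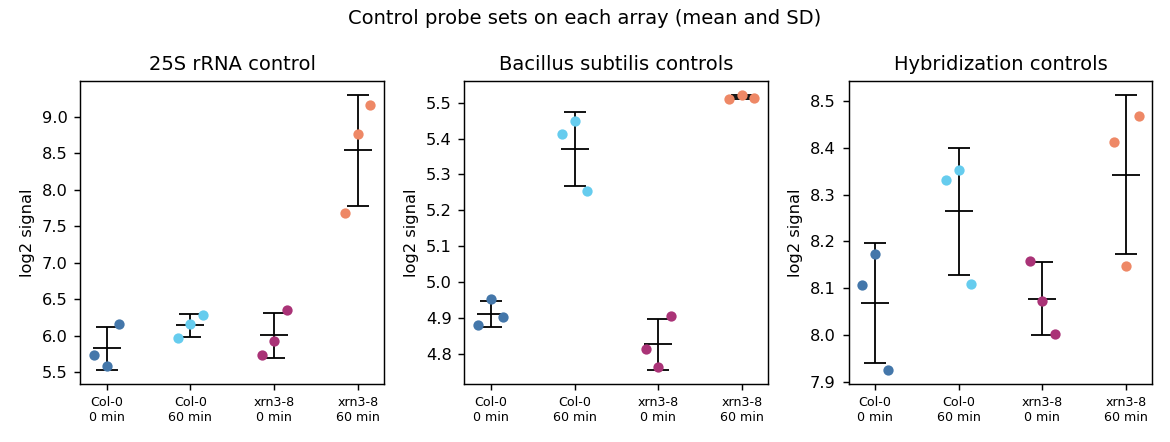
Log2 signal (y axis) of the 25S ribosomal RNA control, the mean of 12 Bacillus subtilis controls and the mean of 18 hybridization controls on each array (points) by group (x axis), with the mean and SD of 3 arrays. The 25S control stood at 5.83, 6.14 and 6.01 in Col-0 before and after cordycepin and xrn3-8 before it, and at 8.54 in xrn3-8 after it.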

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

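The test of the interaction was planned before the data were examined, the extended ribosomal protein list was written after the probe annotation and before any fold change was seen, and the tests of the 25S control and of the scaling of ribosomal protein genes were chosen only after those results were seen, as were the splits with equal exchange.

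A difference between the genotypes in the change after cordycepin, tested as an interaction, singled out 1830 probe sets. Among 100 splits drawn from 200, 3 gave as many calls, the real one and 2 others, the highest with 2053. Both others exchanged the genotype labels of 3 array pairs at 60 min and of 1 at 0 min, so they carry the genotype difference into the interaction by construction, which is sample structure. The interaction was positive for AT3G13760 (1.683), AT4G32350 (1.517), AT1G51090 (1.393), AT1G22810 (1.387), AT1G54050 (1.363) and AT3G62590 (1.353). Among genes with a symbol, it was positive for EXLA2 (1.197), ELC (1.143), KICP-02 (1.137), XTH33 (1.127), psbD (0.980) and UGT85A2 (0.970). It was negative for AT5G01700 (-3.710), AT1G74400 (-2.583), AT2G18100 (-2.513), AT4G27270 (-2.397), AT1G76170 (-2.340) and AT1G19190 (-2.313). Among genes with a symbol, it was negative for NRPD7 (-2.060), MBAC1 (-1.280), BHLH101 (-1.083), EXPA4 (-1.043), MAP1B (-1.0) and PDF1.2 (-0.900).

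The extended list of ribosomal protein genes had a median interaction of -0.205 and was singled out by the same test, but had adjusted p = 0.148 with an estimated correlation. At least 1 list was called in 72 of 100 drawn splits, with at most 3 lists in a split, and in 27 of the 38 with equal exchange of genotype labels at both times, so a count of 1 list does not stand apart from chance. The median of the list lay below those of all 10000 lists of genes matched on signal (lowest -0.105).

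The same ribosomal protein list was higher in xrn3-8 before cordycepin (median 0.283), with adjusted p = 0.0622 with an estimated correlation. Ribosomal protein genes have high signals, but 10000 lists of genes matched on signal had medians with an upper percentile bound of 0.117 and a maximum of 0.203, which argues against a normalization that depends on the signal. The scaling of the arrays is argued against by the lowest median under 4 other scalings, 0.249. A test of cross-hybridizing probe sets was planned and was void, because all 72 chosen probe sets lack the suffix that marks them, and the scaling test replaced it. At least 1 list was called in 10 of 10 splits of these 6 arrays, so a count of 1 list does not stand apart from chance here either. What also stays open is genotype against any other difference between the seedlings of the 2 lines, which the 6 arrays do not separate.

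The 25S ribosomal RNA control, outside the main measurement, was higher by 2.533 in xrn3-8 after cordycepin, on 3 arrays with 7.69 to 9.16 against 6.01 ± 0.31 (SD, n = 3) in xrn3-8 before it. Brighter hybridization or scaling of these arrays is argued against by the highest rise of any hybridization control, 0.50. More labelling of RNA other than nuclear messenger RNA stays open. Of 20 plastid genes of middle signal, the highest rise was 0.933 and the median 0.437, below the rise of the 25S control. Their median nevertheless lay above the 0.09 of all probe sets in xrn3-8. The comparison cannot decide, because plastid and ribosomal RNA need not rise equally. The interaction of the 25S control was 2.220 ± 0.376 (SE, adjusted p = 0.00173), but a single control probe set on 3 arrays cannot separate genotype and cordycepin together from the handling of that 1 group, which stays open.

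The Bacillus subtilis controls, also outside the main measurement, rose after cordycepin by 0.460 in Col-0 and by 0.689 in xrn3-8. The stage at which these controls were added is not given in the sources used here.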

How the results depend on the processing

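Centring on Bacillus subtilis or hybridization controls and both flanking gene tests were chosen only after the data were seen; the other alternatives were planned. Of 115 values of genes named for the largest changes, 0 reversed under any alternative, while 2720 alternative values stayed past the threshold and 7 did not. These genes were chosen for the size of their change on the same arrays. The largest mean shift of the controls was 0.689, so the selection left little room for a reversal. Among called members of planned lists, 7 of 20 in Col-0 and 13 of 19 in xrn3-8 changed sign after cordycepin under a scaling. Of 18 list calls by camera, 307 alternative values stayed past the threshold, 35 did not and 0 reversed direction. Camera compares the members of a list with the other genes, whereas medians of the lists did turn under centring. Requiring a 2-fold change left 592 and 719 probe sets for genotype before and after cordycepin, 1309 and 891 for cordycepin in Col-0 and xrn3-8, and 182 for the interaction, and an adjusted p under 0.01 left 771 for the interaction; stricter thresholds call fewer by construction. Hybridization control centring gave 4419, 4742, 6732, 5848 and 607 in the same order and 2587 shared genotype calls. Bacillus subtilis centring gave 16304 and 21166 for cordycepin and 2845 for the interaction. The cause was not tested.

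With an estimated correlation, camera called 0 lists for genotype before cordycepin, 0 for cordycepin in Col-0, 0 in xrn3-8 and 0 in the interaction, while fry called 18, 16, 32, 32 and 2 lists in the 5 contrasts. With hybridization control centring, camera called 2 for genotype before cordycepin and 2 in the interaction. The adjusted p of the early auxin list in Col-0 was 0.245 with an estimated correlation and 0.0695 with centring on housekeeping and ribosomal protein genes, over a range of 0.00556 to 0.245 for camera. In xrn3-8 it was 0.254 with an estimated correlation, over a range of 2.70e-04 to 0.254 for camera. Under fry, which tests against no change, it was 2.56e-05 in both. The difference in flanking signal, 0.453, was 0.139 against genes matched on signal, so own signal level accounts for most of it. The cause of the changes in list calls was not tested.

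Leaving out each array in turn gave 5815 to 7685 and 6312 to 7321 probe sets for genotype before and after cordycepin, 9337 to 10930 and 7538 to 9195 for cordycepin in Col-0 and xrn3-8, 1233 to 1704 for the interaction and 3674 to 4279 shared genotype calls. Lists called were 1 to 3 (3 without array 3 of xrn3-8 before cordycepin), 0, 7, 6 to 11 and 1 to 2 in the 5 contrasts. The early auxin p was 0.0159 to 0.0257 in Col-0 and 0.00353 to 0.00907 in xrn3-8, and the flanking difference 0.419 to 0.473. In xrn3-8 after cordycepin, the ribosomal protein list lost its call without array 2 after cordycepin (adjusted p = 0.0945), as did expansins (0.0870) and plastid genes (0.0575).

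The labels number the replicates but do not say that equal numbers were grown together. With the replicate number as a block, the counts were 7426, 7488, 10661, 9328 and 1940, with 4370 shared. The arrays were not treated as paired in the main fit, as fixed before the data were examined. Residuals of arrays with equal numbers had a mean correlation of 0.040, against -0.020 for unequal numbers. The best match of 7 of the 12 arrays had their own number. Alternatives for the signal of XRN3 and the upstream neighbour as written were not run, nor was a fit of 2 groups for the interaction, which needs 4. Background level and the number of arrays limit small changes of weak probe sets.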

Other observations

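The families below were listed before any fold change was looked at, while the tests of flanking genes, of the genes' own signal and of strongly changed genes were chosen only after the data or the result were seen.

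Of 18 expansin genes, 3 were higher and 2 lower in xrn3-8 before cordycepin, and of 47 UDP-glycosyltransferase genes 8 were higher and 12 lower; camera called neither list (adjusted p = 0.724 and 0.726). The expansin genes EXPA8 (1.58 ± 0.13 SE, n = 3 arrays per group) and EXPA4 (1.21 ± 0.12) were higher in xrn3-8 and EXLA3 (-1.34 ± 0.14) was lower. Among UDP-glycosyltransferase genes, UGT73B1 (1.27 ± 0.12) was higher and UGT76B1 (-1.71 ± 0.11) and UGT72E2 (-1.52 ± 0.14) were lower. Of 12 ubiquitin protease genes, 6 were lower, with an adjusted p of the list of 0.0895 and a median of -0.23. After cordycepin in xrn3-8, 115 of 989 pseudogenes were higher and 11 lower (adjusted p of the list 0.0705), but 2 were higher and 305 lower with centring on housekeeping and ribosomal protein genes, and 0 higher and 980 lower with Bacillus subtilis centring. These genes and lists were chosen for the text after their values were seen.

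Adjacent protein-coding genes were both at least 2-fold lower in xrn3-8 before cordycepin in 7 pairs, against 1.0 in random draws (highest 6, permutation p = 1.00e-04, the smallest that the draws can give). With any annotated gene as neighbour, there were 4 pairs against 0.77 (highest 6, permutation p = 0.00690). The draws take no account of neighbours of the same gene family. The 7 protein-coding pairs, named after their values were seen, included AT1G26240 (-1.15) and AT1G26250 (-4.83), AT1G26380 (-3.12) and AT1G26390 (-3.63), and AT1G26410 (-2.37) and AT1G26420 (-2.41). The others were AT1G67800 (-1.14) and SUFE2 (-1.06), AT2G47550 (-1.48) and AT2G47560 (-1.04), AT4G30450 (-1.23) and AT4G30460 (-1.19), and AT5G38900 (-2.18) and AT5G38910 (-2.87).

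A hypothesis was that transcripts of a strong neighbour run on into genes raised in xrn3-8, which would place these genes beside genes with a strong signal. For genes called higher with a measured flanking gene, matching on own signal left a difference in flanking signal of 0.139 (permutation p = 0.0558). The signal matched on was the mean over all arrays, xrn3-8 included, so this matching cannot tell own signal level from the rise itself. For genes at least 2-fold higher, own signal level is argued against by a matched difference of 0.998. A property of any strongly changed gene is argued against by genes at least 2-fold lower. Their matched difference was -0.535 (permutation p = 0.0122), and -0.168 with protein-coding neighbours (permutation p = 0.405), so neither was positive. Neighbours that rise together are argued against by 0.974 without genes whose strongest neighbour rose (permutation p = 6.70e-04, 61 genes). Sharing of probes was not tested separately. Over the 1150 genes called higher with a measured flanking gene, Spearman's rho of the rise and the neighbour's signal was 0.053 (permutation p = 0.0713). Genes are not independent replicates. Whether transcripts run on stays open, because the strand that separates upstream from downstream neighbours is not in the tables, and genotype itself was tested only as the grouping.

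The arrays were also divided in other ways into groups of the same size. The 6 arrays of a comparison allow 10 splits, too few for a share under 0.05. As many probe sets were called in 1 of 10 splits, the real one, for genotype before cordycepin (7264, highest other 0), genotype after it (7322, highest other 0), cordycepin in Col-0 (10534, highest other 0) and cordycepin in xrn3-8 (9183, highest other 0). As many lists were called in 10 of 10 splits for genotype before cordycepin (1, highest other 3), 1 of 10 for cordycepin in Col-0 (7, highest other 4) and 1 of 10 in xrn3-8 (9, highest other 4). Shared calls of both genotype comparisons were as many in 1 of 100 drawn splits (4268, highest other 0). A shared call needs calls at both times. The other splits of each genotype comparison called 0 probe sets, so their shared calls were bound to be 0. This share therefore says nothing beyond those splits.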
